A study of Caenorhabditis elegans with 3 samples.

How the data were processed

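DNA and poly-A-selected RNA of *C. elegans* strain HC566, grown in liquid culture on *E. coli*, were sequenced on an Illumina instrument as 3 libraries, 1 per group, per the labels. The group of each library, DNA read from both ends, DNA read from 1 end, or RNA, was taken from its title. Per the labels, reads were mapped with TopHat2 to the sequence of plasmid pTG96. The TopHat2 version, its settings and any read trimming or removal of duplicates are not given in the sources used here.

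The deposited junction lists give, for each junction, its coordinates and a count of spanning reads, per the file headers and the layout of the lists. These counts were deposited without normalization, and the number of mapped reads per library is not given in the sources used here, so read numbers of a junction were not scaled between libraries. The authors' deposited summary table gives, for each of 25 rearrangements, a read count, the mean coverage at its edges as a signal and the percent that the reads make up of that coverage. That percent was recomputed from the reads and coverage and differed by 0 in every entry. Positions in that table are 1 lower than the edges used here.

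The deposited reference has 24012 bases, the 12006 bp of pTG96 followed by its reverse complement. Positions are counted from 1 on the plasmid, and a junction is given by the last base before and the first base after the skip, or, for an inversion, by the pair of bases joined. Junctions with both edges in the same copy were classed as deletions and those from the plasmid to its reverse complement as inversions. Only tail-to-tail inversions can appear on this reference, and neither head-to-head joins nor duplications can. A junction and its mirror image on the other copy were counted once, with the higher of both read counts. Junctions listed at shifted edges within the same run of identical bases were not joined, so 1 rearrangement can count more than once. Junctions with an edge before the first base of the reference were left out. They numbered 923, 6 and 43 in the paired-end, single-read and RNA lists, which is 45.1%, 7.50% and 8.45% of the deposited junctions and 11.6%, 0.377% and 0.0110% of the deposited reads.

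The mapper places junctions at splice motifs. Of the 1316 deposited junctions without a motif or with an edge before the reference, 98.9% had exactly the skipped length of a motif junction in the same list, against 5.04% when lengths were moved by 1 to 20 bp. Skipped lengths were taken on the whole reference, so that motif junction can be an inversion as well as a deletion. The results were therefore also computed over motif junctions alone, a choice made after seeing the data. The shortest skips were 61, 51 and 50 bp in the 3 lists. Whether shorter introns or deletions could have been listed is not known.

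The plan for the introns named a reference annotation of *sur-5*. No genome was used here, and the gene model was instead built from the plasmid sequence and the RNA junctions, which departs from that plan. The *sur-5* start codon was placed at 3699, the *gfp* reading frame with its nuclear localisation signal at 7611 and the end of the stop codon at 8522. Junctions with GT-AG ends, at least 1000 RNA reads and both edges inside this span were taken as introns, giving 8 in *sur-5* and 3 in *gfp*. Because the RNA reads define these introns, all of them have RNA reads by construction. An open reading frame through to *gfp* needs 4 further introns of 40 to 47 bp, which can be placed in 8 ways and would give a protein of 972 to 977 amino acids. Parts of the plasmid were the region upstream of *sur-5* (1 to 3698), *sur-5* (3699 to 7610), *gfp* (7611 to 8522) and the rest (8523 to 12006). The ampicillin resistance gene lies at 9856 to 10716. The 3' UTR was not told apart from the vector. Reads of the worm's own *sur-5* gene map to the plasmid too and cannot be separated.

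Counts have exact Poisson and shares exact (Clopper-Pearson) binomial 95% intervals, and a count of 0 allows up to 3 reads. Reads are not independent molecules, so intervals cover counting error only. Shares of inversions were compared by two-sided Fisher's exact tests. Overlaps, edge locations, deletion sizes and identical bases at edges were tested by permutation with 100000 draws, against random edge pairs of the same class and motif, circular shifts of the plasmid or shuffled libraries. For overlaps, each junction was drawn as matched or not at the rate of random pairs, without regard to identical bases at its edges. Random pairs for the identical bases came from pools of 20000, and those for deletions, but not inversions, had skips of at least 50 bp. Adjusted p-values are Benjamini-Hochberg over the tests of each kind, with a threshold of 0.05. Tests treat distinct junctions as independent, although junctions that share an edge or repeat a skipped length are not.

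The junctions named were fixed by rule before the data were examined: the 5 with the most reads per library and class, up to 10 shared by the DNA libraries and up to 10 shared by RNA and DNA with the most reads in total, up to 15 RNA junctions at introns, and the first 15 entries of the authors' deposited table. The deletions of the ampicillin resistance gene, the pairs of intron copies, the intron after *gfp* and the *gfp* introns in the authors' deposited table were named after their values had been seen.

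Alternatives fixed before the data were examined were minimums of 2 and 5 reads, mirror images counted apart or their reads summed, edges equal within 5 or 10 bp, introns left out, deletions of at least 200 bp, aligned blocks of at least 15 bp, motif junctions alone for the share of inversions, and paired-end reads thinned to the single-read total in 100 draws. Motif junctions alone for the other results, random pairs of like span, and leaving out the inversion with the longest run of identical bases, were added after seeing the data. For mirror images counted apart and edges within a tolerance, intron reads were summed over all matching junctions, a definition set after a first run had taken the highest.

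The scripts were tested on simulated data. Of 400 simulated rearrangements written to lists, 400 were recovered with 0 false ones. Of 60 location tests on uniform simulated junctions, 2 gave p under 0.05, and of 20 tests of identical bases on simulated pairs, 0 did. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, Biopython 1.88 and matplotlib 3.10.9 was used.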

Results

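Strain HC566 of the nematode *Caenorhabditis elegans* carries an integrated, repetitive array of the plasmid pTG96, which fuses the gene *sur-5* to *gfp*. SUR-5 is related to acetoacetyl-CoA synthetases, and GFP is the green fluorescent protein used as a reporter. From mixed-stage liquid cultures, 3 libraries were made, 1 per group: a paired-end DNA library, a single-read DNA library and a library of poly-A-selected RNA. Each library has a list of junctions, places where a read continued at a distant position of the plasmid. A junction within 1 copy of the plasmid was read as a deletion in DNA, or as a deletion or splice in RNA. A junction that crossed from the plasmid to its reverse complement was read as an inversion. Such a junction does not tell an inversion within a copy from a join between copies in opposite directions. The questions were which deletions and inversions the transgene DNA carried and which spliced, deleted or inverted forms its RNA carried. With 1 library per group there are no replicates, so every test below compares libraries, not conditions, and intervals cover counting error only.

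The paired-end list held 2045 junctions with 147406 spanning reads, the single-read list 80 junctions with 10351 reads, and the RNA list 509 junctions with 616560 reads. After joining mirror images and setting aside junctions with an edge before the start of the reference, 809, 50 and 372 distinct junctions remained, with 83417, 7536 and 340270 reads.

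Inversions outnumbered deletions in the paired-end DNA library. In the other libraries the order depended on whether junctions without a splice motif were counted. In paired-end DNA, 601 distinct inversions (95% exact Poisson interval 554 to 651) stood against 208 deletions (181 to 238). In single-read DNA there were 21 inversions (13 to 32.1) and 29 deletions (19.4 to 41.6), and in RNA 138 inversions (116 to 163) and 234 deletion-like junctions (205 to 266). Inversions held 70057 of the paired-end reads, whereas deletion-like junctions held 321530 of the RNA reads. Of the deletions, 71, 14 and 85 in the same order of libraries had a splice motif at their ends, and nearly all the others had the exact skipped length of a motif junction in the same list, so the deletion counts depend on whether these others are kept. Inversions with a motif numbered 569, 20 and 129, so over motif junctions inversions outnumbered deletions in single-read DNA and RNA too.

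The inversions with the most paired-end reads lay in *sur-5*, upstream of it and in *gfp*. The join of positions 5993 and 6262 of pTG96, inside *sur-5*, had 4192 reads. The join of 270 and 522, upstream of *sur-5*, had 3597, and that of 7854 and 8079, in *gfp*, had 2993. The join of 8818 and 8920, downstream of *gfp*, followed with 1378 reads, and that of 1347 and 1629 with 1175. The single-read library had none of the joins at 5993, 270, 7854 and 1347, but had 1038 reads at 8818 to 8920. Its inversion with the most reads joined 1814 and 2260, upstream of *sur-5*, with 1687 reads against 413 in paired-end DNA, and these edges lie in an inverted repeat of 51 identical bases. After it and the join of 8818 and 8920 came those of 1926 and 11906 (476 reads), 8628 and 11056 (460) and 8971 and 9169 (411).

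Among deletions, the paired-end library had the most reads at 5883 to 8316, from *sur-5* into *gfp*, with 1788. The deletion from 7835 to 8041 in *gfp* had 1452 reads, that from 5084 to 6017 in *sur-5* had 832, and that from 8079 to 8295 in *gfp* had 774. A junction from 3579 to 6012, with 554 reads and no splice motif, had the same skipped length, 2432 bp, as the 5883 to 8316 deletion. In single-read DNA the leading deletions were 5930 to 6070 in *sur-5* (472 reads), 8255 to 11907 from *gfp* into the vector (388), 7835 to 8041 (352), 8028 to 8080 (263) and 3337 to 8706, which spans *sur-5* and *gfp* whole (229).

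**Figure D1:**
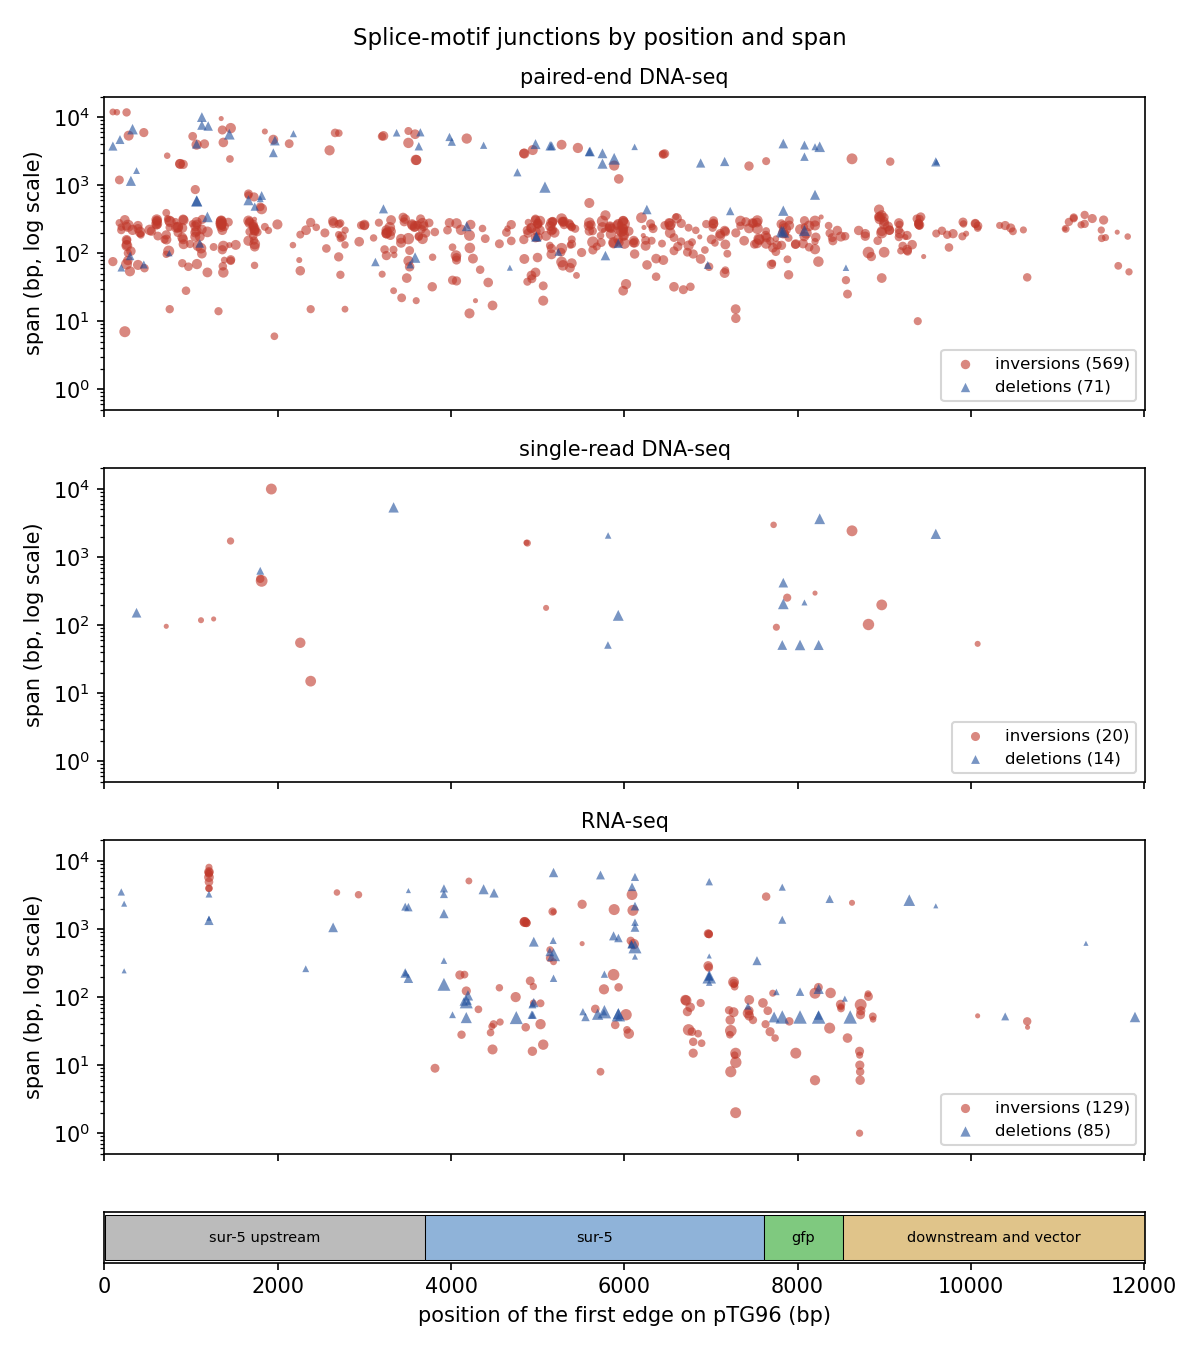
Junctions with a splice motif in each library. The horizontal axis gives the position of the first edge on pTG96 in bp, the vertical axis the distance between the edges in bp on a log scale, circles are inversions, triangles are deletions, and larger symbols have more reads. The 569 paired-end inversions form a band with a median span of 211 bp along the plasmid, while the 129 RNA inversions have a median span of 77 bp and lie mostly over *sur-5* and *gfp*.

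Inversions made up a larger share of distinct junctions in paired-end DNA than in the other libraries. The share was 74.3% (95% exact binomial interval 71.1 to 77.3) in paired-end DNA, 42.0% (28.2 to 56.8) in single-read DNA and 37.1% (32.2 to 42.2) in RNA. The share in paired-end DNA was higher by 32.3 points than in single-read DNA (two-sided Fisher's exact test, adjusted p = 6.4e-06 over 3 pairs). It was higher by 37.2 points than in RNA (exact test, adjusted p = 1.5e-33). Single-read DNA and RNA differed by 4.90 points, which the exact test did not separate (adjusted p = 0.54). These shares count as deletions the junctions without a motif, some of which repeat the skipped length of an inversion. Over motif junctions the shares were 88.9% (86.2 to 91.2), 58.8% (40.7 to 75.4) and 60.3% (53.4 to 66.9), and the same pairs of libraries passed the threshold. The DNA libraries differ in read layout, so their difference in share cannot be assigned to the DNA rather than to the layout.

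The DNA libraries had 19 junctions in common with both edges equal, 7 deletions and 12 inversions. In 100000 draws, with each junction matched at the rate of random edge pairs of the same class and motif, none shared as many. These draws took no account of identical bases at the edges, of which the shared junctions had up to 51. They thus do not tell shared rearrangements from joins that recur at repeated sequence. The mean number shared in the draws was 0.0110, or 0.108 for random pairs of like span. With either, the one-sided permutation p of 1e-05 is the smallest these draws can give. Of the shared deletions, 2 remove the whole ampicillin resistance gene of the vector, 8255 to 11907, with 319 paired-end and 388 single-read reads, and 9595 to 11788, with 54 and 191. The most deeply read shared inversions were 8818 to 8920, 1814 to 2260, 8971 to 9169 (582 paired-end reads) and 8628 to 11056 (469). The joins of 8201 and 8496 in *gfp* and of 2380 and 2395 had 577 and 16 paired-end reads but 1 and 382 single-read reads, so the read numbers of a shared junction could differ widely between libraries.

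Shared deletions fell largely on the short artificial introns of the plasmid. Introns of 51 bp that begin GTAAGTTTAAAC and end TTTAAATTTTCAG occur 5 times on pTG96. Their first bases are 7824, 8029 and 8244 in *gfp*, 8608 after its stop codon and 11895 in the vector. They are called copies here for these shared ends, and are not all identical between them. Of the 7 deletions shared by the DNA libraries, 4 joined 2 of these copies, with 13 to 18 identical bases at the edges. They were 7835 to 8041, 7835 to 8256, 8079 to 8295 and 8255 to 11907. Random edge pairs joined 2 copies in 0.0360% of 200000 draws. This count was chosen after the positions had been seen.

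RNA reads spanned the introns of *sur-5* and *gfp*, as the gene model, built from RNA junctions with at least 1000 reads, requires. All 8 *sur-5* introns of at least 50 bp and all 3 *gfp* introns had spanning reads, 250077 in total, or 73.5% of RNA junction reads (95% exact binomial interval 73.3 to 73.6). The *sur-5* introns had 11774 to 36209 reads each. The lowest was the intron that starts at 3919 and the highest the one that starts at 6981. Those starting at 4177, 4754, 5184 and 6124 had 13208, 15279, 14702 and 14455 reads, and those at 5771 and 5933 had 27022 and 27077. The *gfp* introns had 25673, 30464 and 34214 reads in order along the gene. Reads of *sur-5* introns can also come from the worm's own *sur-5* gene, whereas *gfp* reads come from the transgene alone. An intron after the *gfp* stop codon with the same first and last bases as those of *gfp*, starting at 8608, had 28459 RNA reads.

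In DNA, the *sur-5* introns had no spanning read in either library, which for counting error alone allows a share of up to 0.0398% of junction reads in single-read DNA and 0.00360% in paired-end DNA. The shortest skips listed were 51 and 61 bp, so the *sur-5* intron of 50 bp, and in paired-end DNA also that of 55 bp, lie below the lengths seen. The 3 *gfp* introns had none in paired-end DNA, whose list holds no skip as short as these 51 bp introns. In single-read DNA they had 102, 263 and 149 reads, together 6.82% of junction reads (6.26 to 7.41).

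**Figure D2:**
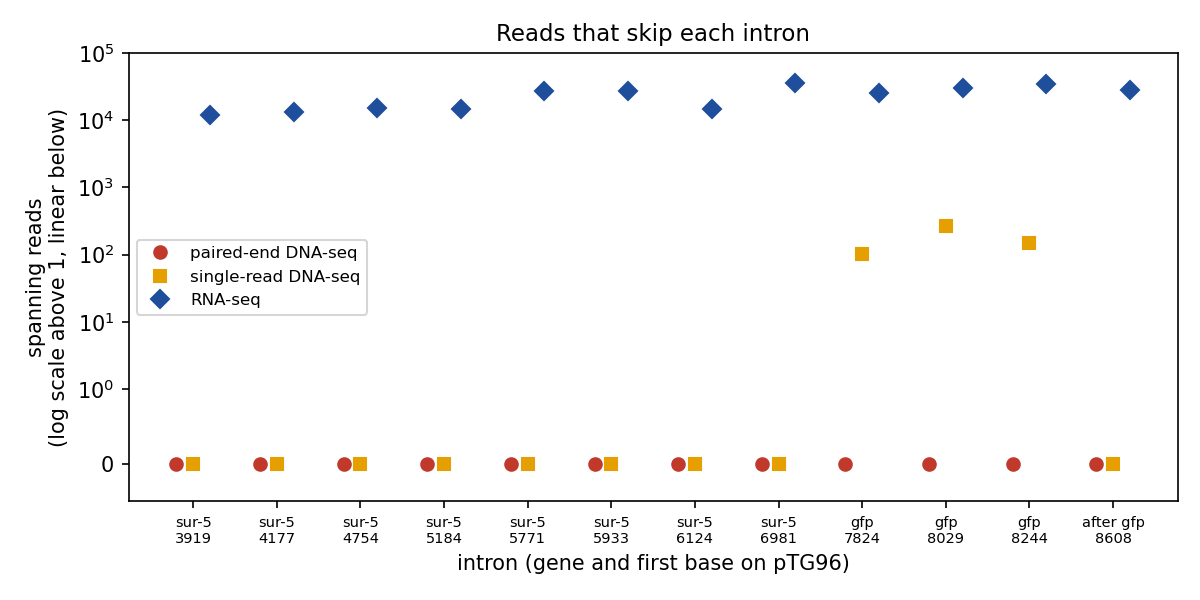
Reads that skip each intron, per library, by gene and first base of the intron on pTG96. The vertical axis gives spanning reads on a log scale above 1 and a linear scale below, with 1 symbol per library and intron. RNA lies between 11774 and 36209 reads at the *sur-5* and *gfp* introns and at 28459 after *gfp*, single-read DNA has 102 to 263 reads at the *gfp* introns and 0 elsewhere, and paired-end DNA has 0 throughout.

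RNA and DNA had 19 junctions with equal edges, 6 deletion-like and 13 inversions, against a mean of 0.0604 over 100000 draws of random pairs and 0.557 for pairs of like span (one-sided permutation tests, p = 1e-05 for both, the smallest the draws can give). These draws too took no account of identical bases at the edges. The shared deletion-like junctions included the 3 *gfp* introns and 7831 to 7883, an intron-sized skip next to the *gfp* intron that starts at 7824, with 957 RNA and 122 single-read DNA reads. Among the inversions, 7287 to 7298 in *sur-5* had 908 RNA reads and 65 paired-end reads. The join of 5883 in *sur-5* and 7814 in *gfp* had 585 and 163, that of 8201 and 8315 in *gfp* had 557 and 176, and that of 7285 and 7300 had 468 and 107. The joins 7287 to 7298 and 7285 to 7300 have nearby edges with 7 identical bases each. They may thus be 1 rearrangement listed at different edges. The inversion 8818 to 8920, found in both DNA libraries, had 32 RNA reads, and 8628 to 11056 had 2. The RNA inversions with the most reads were not in either DNA list. They joined 8728 and 8805 (2170 reads), 5876 and 6089 (1379), 7229 and 7261 (1357), 6742 and 6775 (1117) and 6020 and 6075 (1021).

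Junction edges were unevenly spread over the plasmid. Of 24 tests over 4 plasmid parts, 3 libraries and both classes, 15 passed an adjusted p of 0.05 (two-sided circular-shift permutation test, smallest adjusted p 4.8e-05). Edges of RNA deletion-like junctions lay in *gfp* 3.43 times and in *sur-5* 1.55 times as often as its length would give, and upstream of *sur-5* and downstream of *gfp* 0.437 and 0.346 times as often. Edges of RNA inversions lay in *sur-5* 1.92 times (adjusted p = 4.8e-05) and in *gfp* 2.05 times as often (permutation test, adjusted p = 0.0015), and upstream of *sur-5* 0.165 times. In DNA, deletion edges lay in *gfp* 2.37 times as often in the paired-end and 6.13 times in the single-read library. Paired-end inversions had 0.582 times the edges downstream of *gfp* and in the vector, and 1.42 times in *gfp*. Unevenness was not compared between libraries, whose numbers of junctions differ. The random shifts take no account of read coverage, which in RNA follows the transcribed parts. The RNA values therefore do not tell where junctions form among transcribed bases. Over junctions with a splice motif alone, 14 of the 24 tests passed, and the excess of RNA deletion-like edges was 1.86 times in *gfp* and 1.82 times in *sur-5*. The excess of DNA deletion edges in *gfp* was 1.85 times in the paired-end library (permutation test, adjusted p = 0.041) and 6.58 times in the single-read library. The single-read deletions include the 3 *gfp* introns. The excess of paired-end inversions in *gfp* (1.25 times, permutation test, adjusted p = 0.12) and the deficit of paired-end deletions in *sur-5* (0.590 times over all, 0.973 times over motif junctions, adjusted p = 0.91) then no longer passed. A deficit of paired-end deletion edges downstream of *gfp* and in the vector passed only there (0.961 times over all, adjusted p = 0.66, and 0.655 times over motif junctions, permutation test, adjusted p = 0.037).

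Deletions were longest in paired-end DNA when junctions without a splice motif were counted. The median skipped length was 5334 bp (interquartile range 2171 to 6361) in paired-end DNA, 139 bp (51 to 420) in single-read DNA and 84 bp (51 to 547) in RNA. The difference was 5195 bp between the DNA libraries and 5250 bp between paired-end DNA and RNA (two-sided permutation tests, adjusted p = 1.5e-05 for both). Single-read DNA and RNA differed by 55 bp (permutation test, adjusted p = 0.34). Over deletions with a splice motif, the medians were 1632, 210 and 243 bp, and the DNA libraries no longer differed past the threshold (1422 bp, permutation test, adjusted p = 0.45). Paired-end DNA and RNA still did (1389 bp, permutation test, adjusted p = 0.0012).

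Nearly all inversions had a splice motif, GT-AG, GC-AG or AT-AC, which random edge pairs have in 1.79% of cases for inversions and 2% for deletions. The motif share of inversions was 94.7% (95% exact binomial interval 92.6 to 96.3) in paired-end DNA, 95.2% (76.2 to 99.9) in single-read DNA and 93.5% (88.0 to 97) in RNA. For deletions it was 34.1% (27.7 to 41.0), 48.3% (29.4 to 67.5) and 36.3% (30.2 to 42.8), but these junctions held 80.5%, 84.1% and 88.4% of the reads. AT-AC was the most frequent motif of inversions, with 360 against 130 for GT-AG in paired-end DNA and 52 against 49 in RNA. Among deletions with a motif, 46 were AT-AC and 21 GT-AG in paired-end DNA, while 14 were AT-AC and 67 GT-AG in RNA. Rearrangements without such a motif lay largely outside what the lists can show.

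DNA junctions shared sequence at their edges. Identical bases averaged 2.15 bp at paired-end deletions and 3.61 bp at paired-end inversions, where random pairs of the same class and motif gave 0.722 and 0.708 bp. In single-read DNA the means were 3.52 bp at deletions and 6.14 bp at inversions, against 0.687 and 0.758 bp. Each exceeded chance (one-sided permutation tests, adjusted p = 1.2e-05, the smallest the draws can give after adjustment). Over motif junctions alone the paired-end means were 5.03 bp at deletions and 3.78 bp at inversions, so the order of the classes turned, and the mean at single-read deletions was 5.79 bp. Without the inversion in the 51 bp repeat, the mean at single-read inversions was 3.90 bp (permutation test, adjusted p = 1.2e-05). Outside the introns, RNA deletion-like junctions averaged 0.865 bp against 0.671 bp (permutation test, adjusted p = 0.0033), and RNA inversions 1.70 bp against 0.640 bp (permutation test, adjusted p = 1.2e-05). Edges with 5 or more identical bases made up 35.1% of paired-end inversions, 12.3% of RNA inversions and 0.448% of RNA deletion-like junctions outside introns. The difference between libraries was not tested.

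**Figure D3:**
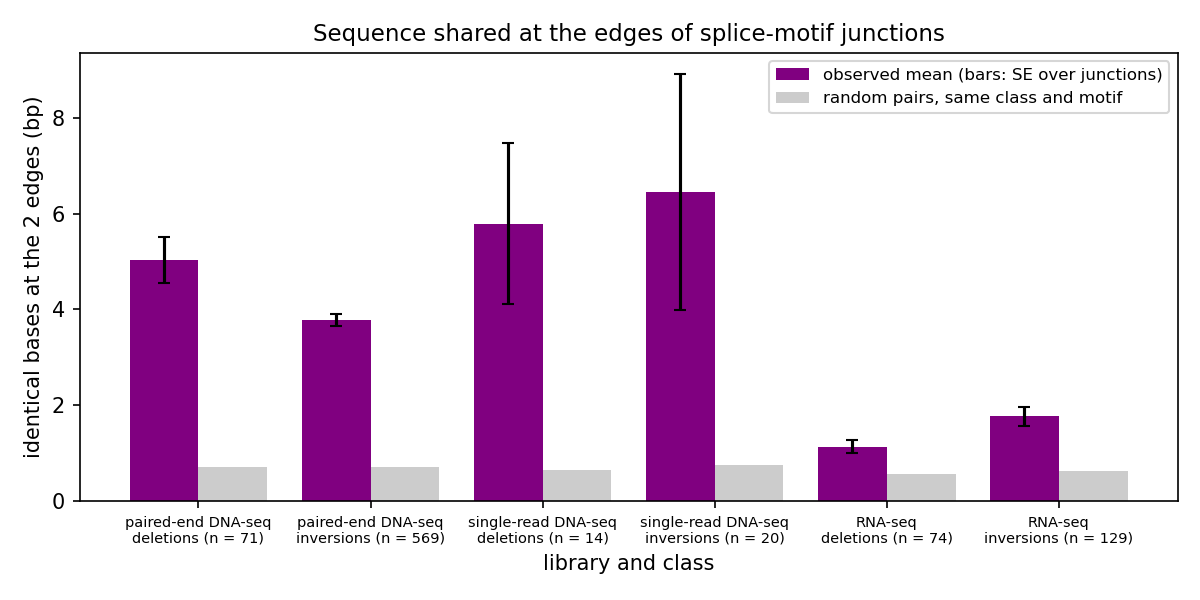
Mean number of identical bases in bp at the edges of junctions with a splice motif, by library and class, beside random pairs of the same class and motif. Bars start at 0 and error bars are standard errors over junctions, not over replicates. The DNA means lie between 3.78 and 6.45 bp, the RNA means at 1.14 bp for deletions outside introns and 1.77 bp for inversions, and the random pairs between 0.566 and 0.760 bp.

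The authors' deposited table summarises 25 rearrangements, 16 inversions and 9 deletions, each as a percentage of the mean read coverage at its edges. In the authors' deposited table, inversions made up 3.25% to 21% of coverage and deletions 1.47% to 7.25%, at a mean coverage of 4915 to 13289.5. By the authors' deposited table, the highest share was 21%, for the join of 270 and 522 upstream of *sur-5*, followed by 18% for 5993 to 6262 in *sur-5* and 14% for the join given there as 8357 and 8610. The authors' deposited table gave 9.07% for 7854 to 8079 in *gfp*, 6.85% for 1347 to 1629, 5.65% for 8818 to 8920 and 4.98% for 8201 to 8496. The other first 15 entries of the authors' deposited table, by the positions given there, were 3746 and 4024 (8.31%), 7438 and 7669 (7.31%), 6528 and 6794 (6.83%), 1731 and 2045 (5.96%), 3670 and 3943 (5.15%), 5747 and 6041 (5.13%), 5875 and 6172 (3.71%) and 1346 and 1610 (3.25%). Its first 15 entries, all of them inversions of 102 to 314 bp credited to the paired-end library, ranged from 3.25% to 21% in the authors' deposited table. The entry for 8818 to 8920 is credited there to the single-read library too. Of the 25 entries, 22 were found in the junction lists, and 2 of the 3 others are marked in the authors' deposited table as found in a fusion mode of the mapper, whose output was not used here. Of these 15 inversions, 2 were also in the single-read list, 8818 to 8920 with 1038 reads and 8201 to 8496 with 1. The 3 *gfp* introns stand among the deletions in the authors' deposited table, with 1.47%, 3.46% and 1.51% of coverage in order along the gene. Read numbers in the authors' deposited table equalled a value in the lists for 3 of the 25 entries, so its percentages rest on other read numbers than those given above. Both could differ widely, as at 8357 and 8610, with 1234 reads in the authors' deposited table and 9 in the paired-end list, at 3746 and 4024, with 862 and 29, and at 1731 and 2045, with 637 and 1.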

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

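Junctions with an edge before the first base of the reference had reads but entered no comparison of the report other than that of skipped lengths. They numbered 923 in paired-end DNA (17037 reads), 6 in single-read DNA (39 reads) and 43 in RNA (68 reads), each read total above the 3 reads that a count of 0 allows. Of them, 911, 6 and 41 had exactly the skipped length of a splice-motif junction in the same list. No explanation was tested for these junctions.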

How the results depend on the processing

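Of 188 values recomputed under alternatives for 31 results, 158 kept their direction and side of the threshold or moved by less than the limits set, 23 moved, 6 reversed and 1 lost its call. Motif junctions alone (except for the share of inversions), random pairs of like span, and leaving out the longest repeat were chosen after seeing the data. The causes were not tested.

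The reversals all concern single-read DNA minus RNA, which passed no threshold in any setting. The median deletion size became -10 bp with at least 2 reads, -4 bp with at least 5, -532 bp over deletions of at least 200 bp and -33 bp over motif junctions. The inversion share became -3.41 points with at least 5 reads and -1.46 points over motif junctions.

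The call that ended was the size of paired-end minus single-read deletions, 1422 bp (permutation test, adjusted p = 0.45) over motif junctions. Motif junctions alone also gave 71, 14 and 85 deletions in paired-end DNA, single-read DNA and RNA, and 82.5% of RNA junction reads at introns. With at least 2 reads, the motif share of single-read inversions was 100%. With at least 5 reads, single-read inversions numbered 12, DNA libraries shared 12 junctions, and motif shares were 44.4% of paired-end deletions and 96.6%, 100% and 99.1% of paired-end, single-read and RNA inversions. Mirror images counted apart gave 34 single-read inversions, 35 junctions shared by the DNA libraries, 35 shared by RNA and DNA, 78.9% of RNA reads at introns, and motif shares of 43.4% and 96.4% of paired-end deletions and inversions and 47.2% of RNA deletions. Summed mirror reads also gave 78.9% at introns. Edges within 5 bp gave 74.1% at introns, and within 10 bp 74.7% with 33 junctions shared by RNA and DNA. Thinned to the single-read total, paired-end DNA had a median of 129.5 deletions, while its inversions, with a median of 510, stayed within the limit.

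No paired analysis was possible because each group has 1 library. For the same reason no library was left out or regrouped.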

Other observations

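All tests in this part were chosen after the results had been seen, and for the comparison with the acceptor consensus the outcome was stated before it was computed.

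Beyond the gene model, 48 further forward GT-AG skips were found in RNA, with 31078 reads, of which 3 had 100 or more. After the intron at 8608 came a splice from 9289 to 11946, which skips 2656 bp of vector including the whole ampicillin resistance gene and had 1403 reads. The copy of the artificial intron in the vector, starting at 11895, had 262 reads. Neither had a read in DNA. Near the *sur-5* start codon, RNA was joined to the base before it, 3698, from 2639, 3471 and 3508, with 92, 78 and 69 reads.

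Some RNA inversions began at splice donors of the transgene. Of the 49 GT-AG inversions in RNA, 15 had an edge at a splice donor, with 761 reads. Donors were the last bases before the introns of the gene model and, outside it, before the splices from 8607 and 9289 downstream of *gfp*. The most deeply read joined the donor at 9289 to antisense sequence from 6089 (419 reads), that at 6980 to antisense from 1206 (94) and that at 6123 to antisense from 4848 (91). The donors at 5183, 6123, 6980 and 9289 were all joined to 1206. In paired-end DNA, 4 of 130 GT-AG inversions had such an edge.

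These joins, 30.6% (95% exact binomial interval 18.3 to 45.4) of RNA GT-AG inversions against 2.04% of random GT-AG pairs, may be splicing from a donor of the transgene into the antisense strand of a copy in the opposite direction. At the 9 antisense positions joined, the 5 bases before the AG matched the worm acceptor consensus TTTTC at 3.11 bases on average, against 1.40 at 629 antisense AG sites (one-sided permutation test, p = 4e-05). Position 1206 matched at 5 bases, 6089, with the most reads, at 3, 2683 at 2 and 6975 at 0. GT-AG pairs drawn evenly over the plasmid would have given 0.9996 such junctions, and 15 were seen. Molecules joined during library preparation need not be spread evenly over the plasmid, so this number does not exclude them. The 15 joins used 5 donors and 9 antisense positions and are not independent. Spliced reads placed on similar antisense sequence would need near-identical bases. At most 11 of the first 20 antisense bases matched the start of any exon of the model or after the splices downstream of *gfp*, with aligned blocks of at least 21 bp. The antisense positions 1206 and 6089 were also edges of RNA skips within 1 copy, with GT-AG ends on the antisense strand. These ran from 1206 to 2545 (53 reads) and from 6089 to 10262 (23 reads). Whether the joins come from copies in opposite directions stays open, and other origins were not tested. None of this was tested for the other RNA inversions.

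The *gfp* introns were missing from some single-read DNA reads. Carry-over of RNA would have brought the 7 *sur-5* introns no shorter than the shortest listed skip in the same ratio, 822 reads where 0 were seen, which allows up to 3. DNA of *gfp* without introns stays open, since no independent test of it was found. Whether the strain carries such copies cannot be told apart from DNA of another origin. The shortest skip in the paired-end list, 61 bp, is longer than these introns, and whether that list could hold shorter ones is not known.

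Inversions in paired-end DNA were short. Of those with a splice motif, 91.0% spanned up to 500 bp, against 8.13% of random pairs, and the share was 70.0% in single-read DNA and 76.0% in RNA. The single-read list had 3 of the 20 motif inversions with the most paired-end reads (537 to 4192). Over the 19 motif junctions shared by the DNA libraries, the ratio of single to paired reads had a median of 0.706 and ran from 0.00173, from 1 against 577 reads, to 23.9. The 17 absent inversions had 21108 paired-end reads. These would bring 14906 single reads at the median ratio, 36.6 at the lowest ratio and 0.926 at its lower counting limit, where none was seen. Of the 71 paired-end deletions with a motif, 64 were absent from the single-read list too. The ratios come only from junctions found in both lists, so they need not hold for the absent inversions. Presence of the inversions at the median ratio would have shown in the single-read list. Presence there at the lower limit of the lowest ratio cannot be told apart from presence in the paired-end library alone.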
